A study of Mus musculus with 6 samples.

How the data were processed

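The series measured messenger RNA in the aortas of mice lacking the long noncoding RNA gene Mymsl (KO) and of wild-type mice (WT), with 3 libraries per genotype. Per the labels' protocols, the RNA came from smooth muscle cells purified out of the medial layer, and libraries were made with a stranded poly(A) kit (Illumina TruSeq). The deposited table holds raw read counts per gene, as whole numbers, in 53735 rows and 6 columns. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.6.0c and featureCounts of Subread 1.6.1, and the genome build was GRCm38. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. They decide how reads of overlapping, antisense or near-identical genes were split, so counts of such genes are uncertain. Each column was assigned to its library by the name that the labels give to that library.

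Rows carry gene symbols. Against GENCODE M21 on GRCm38, 28453 rows matched by symbol and 250 by an older symbol, and matched rows held 98.55% of all counts. Coordinates below come from that annotation. A further 23090 rows carried names of bacterial artificial chromosome clones, which that annotation does not use, so they have no coordinates here. Among 28418 pairs of neighbouring matched rows on the same chromosome, 99.88% stood in ascending order of start position. No row had a blank or summary name.

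Total counts per library lay between 20048216 and 25521123. For a row at 0 in a whole group, the floor was 3 counts over the summed effective library sizes of that group, and a fold against it is a lower bound. Such floors cover counting error only, since PCR copies were not marked by molecular identifiers.

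The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genotype was the only term, normalization was by trimmed mean of M values (TMM), and rows were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 14145 rows. P-values were two-sided and adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Log2 fold changes are KO over WT, with standard errors derived from the fold change and the F statistic. Levels are in CPM, counts scaled to library size. They were TMM-normalized and are given as mean ± SD of 3 libraries. P-values measure the spread between these libraries: the labels do not say whether each library came from a single mouse. The series text speaks of mice in 3 pairs, without saying what a replicate number shares, so libraries were not paired.

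Before the data were examined, 39 gene lists with 870 genes were fixed, covering smooth muscle functions, general cell processes and markers of other cell types that an aortic dissection can hold. Of these, 37 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01, and adjusted over the 37 lists. Camera asks whether a list ranks apart from the other genes. The same test with a correlation estimated from the data, and fry, were run as alternatives. Fry asks another question, whether a list's genes move on balance in a single direction, and does not compare them with other genes. A list score is the mean over its tested genes of log2 CPM minus the WT mean. Quantities of whole libraries were compared with exact two-sided permutation tests, for which 3 against 3 libraries give no p below 0.1.

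The rule for named genes was fixed beforehand too. It took Mymsl if a row carried that name, and always Myocd, Srf, Acta2, Myh11, Tagln and Cnn1. It took up to 12 called genes per direction by size of change, with KO and WT libraries separated and a mean of at least 1 CPM in either group, where clone names and predicted genes were limited to 2 per direction. With fewer than 5 calls in all, it took the 10 genes with the smallest p as genes that did not pass. For each called list and for the contractile list, it took up to 4 members with the smallest p, and up to 5 genes of largest deviation for a library that stood apart. Some genes that the rule took are not reported here. Neighbours of a called row, Hox genes, clock genes beyond those 5, and mitochondrial gene copies were chosen after their values were seen.

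The alternatives were size factors of DESeq2 1.42.0, the DESeq2 test, limma-voom, no filter, a filter at a mean count of 50, a fold minimum of 1.5, leaving out mitochondrially encoded and hemoglobin genes, the replicate number as a block, and leaving out each library. Added after the data were seen were leaving out 2 libraries together and a covariate, the mean log2 CPM of Hox genes of paralogue groups 9 and above. Transcripts of GENCODE M21 were compared with BLAST 2.17.0.

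Each test was first checked on simulated counts for 14145 genes with 200 changed, 50 at each fold size, in the KO against WT layout. edgeR recovered 26% of genes changed 1.5-fold, 74% of those changed 2-fold, 100% at 4-fold and 98% at 8-fold, with 5 false calls. DESeq2 recovered 52%, 82%, 100% and 98% at those sizes with 31 false calls, and limma-voom 28%, 70%, 100% and 98% with 7. In the simulated lists, camera called the shifted list and 0 of 36 unchanged lists, with either correlation. The simulated genes were drawn independently, so this check cannot speak for lists whose genes move together. The shifted list was moved by a larger log2 amount than the contractile median reported below. Changed genes had a mean of at least 1 CPM, and no library was made to stand apart. The recovered shares therefore need not hold in the data. In the data the estimated correlation was 0.351 for contractile genes and 0.685 for interferon genes.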

Results

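Aortic messenger RNA was compared between mice lacking the long noncoding RNA gene Mymsl and wild-type mice, to ask which transcripts of aortic smooth muscle depend on Mymsl. Each genotype had 3 libraries, and total counts were 23658113, 25521123 and 23506674 in WT replicates 1, 2 and 3 and 20048216, 20881348 and 23243129 in KO replicates 1, 2 and 3. A check for a library entered more than once found none: chi-square per gene between replicates lay between 15.03 and 69.29. Mitochondrially encoded genes held 7.505% ± 1.704 (SD, n = 3) of WT counts and 13.96% ± 4.53 (SD, n = 3) of KO counts, with 18.9% in KO replicate 1. That difference had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow, and so had the lower totals in KO. Of 13 mitochondrial protein genes, 6 had at most 30 counts over the 6 libraries, so they hardly count in this share.

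No row of the table carried the name Mymsl, so the targeted gene was not analysed here under its own name. A single row, RP23-57D10.3, held at least 10 counts in every WT library and 0 in every KO library, and no row showed the opposite. WT replicates 1, 2 and 3 had 314, 378 and 273 counts of it (13.1 ± 1.86 CPM, n = 3), and each KO library had 0. This makes it at least 277-fold lower in KO, against a floor of 3 counts over the KO group (0.0473 CPM). It was the only gene called by edgeR (adjusted p = 0.00527). The call was lost without WT replicate 1 (adjusted p = 0.131) and with the replicate number as a block (0.224), although the counts in KO stayed at 0. The name is that of a clone, without coordinates in the annotation used. In the table the row stood after AC127348.2 and before Fank1 on chromosome 7, 2 rows after Dhx32.

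**Figure D1:**
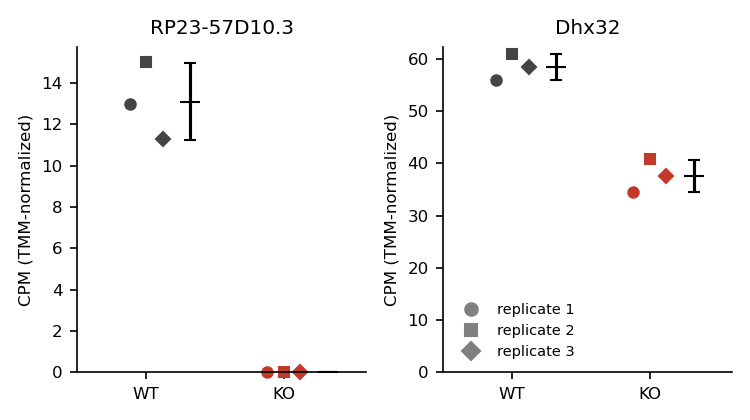
TMM-normalized CPM of RP23-57D10.3 (left) and Dhx32 (right) in each WT and KO library, with the marker shape giving the replicate number and the bar the mean ± SD of 3 libraries. RP23-57D10.3 lies between 11.3 and 15 CPM in WT and at 0 in KO, and Dhx32 lies between 55.9 and 60.9 CPM in WT and between 34.6 and 40.8 in KO.

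Dhx32, which encodes a putative RNA helicase of the DEAH-box family, was the tested gene next to that row. It spans 133720942 to 133782726 of chromosome 7 on the minus strand (GRCm38), and Fank1 starts within its span on the plus strand at 133776861. Dhx32 measured 58.4 ± 2.52 CPM in WT and 37.6 ± 3.12 in KO (n = 3 each), a log2 fold change of −0.63 ± 0.076 (SE). It did not pass over all genes in edgeR (adjusted p = 0.201). It passed in DESeq2, which adjusted over fewer rows (adjusted p = 6.01e-06). Over the 17 tested rows around RP23-57D10.3 alone, a set chosen after the values were seen, its adjusted p was 0.000363. Upstream in the table, Bccip (0.002 ± 0.068), Uros (0.18 ± 0.126), Edrf1 (0.076 ± 0.103) and Ctbp2 (0.051 ± 0.091) had log2 fold changes within 2 standard errors of 0. Downstream, Adam12 had −0.44 ± 0.508 and Dock1 −0.26 ± 0.076 (adjusted p = 0.0507 over the 17 rows). Further downstream, Mki67 (0.91 ± 0.385) and Ebf3 (0.73 ± 0.325) went the other way (adjusted p = 0.196 each over the 17 rows). How reads over Dhx32 and a transcript overlapping it were divided depends on the strand setting of the counting, which is not given in the sources used here.

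**Figure D2:**
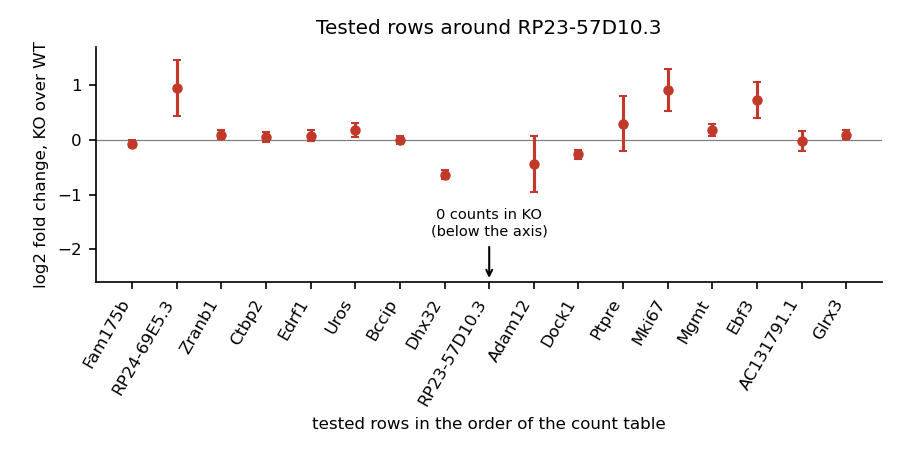
Log2 fold change of KO over WT, with standard error bars, for the 17 tested rows around RP23-57D10.3 in the order of the count table. Dhx32 lies at −0.63, and RP23-57D10.3, with 0 counts in KO, has no fitted point within the axis.

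Across the transcriptome, no gene was higher in KO and 1 was lower among 14145 tested by edgeR. At an unadjusted p under 0.05 there were 962 higher and 1098 lower genes, where chance gives 707 in all. DESeq2 gave an adjusted p to 8467 rows and called 60 higher and 139 lower genes. RP23-57D10.3 had no adjusted p there and was not among them. Limma-voom called the same single row as edgeR. KO and WT libraries did not overlap at 21.8% of genes, where chance gives 10%. After RP23-57D10.3 and Dhx32, the smallest p-values belonged to genes that did not pass in edgeR. Tcirg1, a subunit of the vacuolar proton pump, measured 24 ± 1.1 CPM in WT and 35.9 ± 2.38 in KO (log2 0.58 ± 0.078, adjusted p = 0.239). Wisp1, a secreted matricellular protein gene of the Wnt pathway, measured 17.1 ± 1.25 and 9.28 ± 1.63 CPM (−0.88 ± 0.138). Arhgap5 measured 101 ± 2.73 and 75.6 ± 4.36 CPM (−0.41 ± 0.063). Lysmd3 (−0.47 ± 0.068), Rp2 (−0.40 ± 0.064), Csgalnact2 (−0.33 ± 0.052) and Alg10b (−0.32 ± 0.051) had lower values in every KO library than in any WT library, and all 7 genes from Tcirg1 on passed in DESeq2 with adjusted p between 0.000202 and 0.0151. RP23-8J15.5, a clone-named row, had 1, 5 and 2 counts in WT and 89, 38 and 115 in KO (log2 5.06 ± 0.597, adjusted p = 0.201). In the table it stands between Tubb4b-ps2 and Lmbrd1, where the annotation places near-identical copies of mitochondrial genes, so its count is uncertain.

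The smooth muscle contractile genes ranked lower in KO as a list, by a small amount. Of 35 measured members, 30 had a fold change below 0, with a median log2 of −0.13 (camera adjusted p = 0.000102; adjusted p = 0.692 with an estimated correlation). In edgeR no member passed over all genes or adjusted over the list alone. DESeq2, over the rows to which it gave an adjusted p, called 4 as lower, including Vcl, Itga8 and Pgm5. Actin Acta2, the main thin filament protein of smooth muscle, measured 21800 ± 1010 CPM in WT and 19600 ± 3700 in KO (log2 −0.15, adjusted p = 0.697). Smooth muscle myosin Myh11 had −0.20 (adjusted p = 0.552), Tagln −0.078 (0.8) and Cnn1 −0.058 (0.799). Without KO replicate 1 and without KO replicate 2, Acta2 had −0.05 and −0.31 (adjusted p = 0.931 and 0.295), Myh11 −0.11 and −0.35 (0.82 and 0.272) and Tagln 0.007 and −0.157 (0.991 and 0.541). Over single left-out libraries, Cnn1 lay between −0.122 (without WT replicate 3) and −0.019 (without WT replicate 1). With KO replicates 1 and 3 both left out, these 4 genes had values above 0, from 0.03 for Cnn1 to 0.133 for Acta2. Among the members with the smallest p were the adhesion proteins Vcl (−0.39 ± 0.095), Pgm5 (−0.36 ± 0.104) and Itga8 (−0.41 ± 0.121). Contractile scores in KO replicates 1, 2 and 3 were −0.21, −0.02 and −0.14, lower where the mitochondrial share was higher (18.9%, 10% and 12.98%). In WT replicates 1, 2 and 3 the scores were −0.02, 0.08 and −0.06, higher where the share was higher (7.84%, 9.02% and 5.66%). Their transcriptional regulators, 27 genes around serum response factor and myocardin, had a median of −0.088 (camera adjusted p = 0.0357; adjusted p = 0.692 with an estimated correlation), and 0 passed in edgeR over all genes or adjusted over the list alone, nor in DESeq2. Within them the coactivator Myocd measured 115 ± 11.4 and 87.1 ± 17.9 CPM (−0.40 ± 0.152, adjusted p = 0.303), Srf 128 ± 7.46 and 111 ± 7.43 CPM (−0.20 ± 0.074, adjusted p = 0.293), Tead1 −0.27 ± 0.066 and Wwtr1 −0.24 ± 0.07. The regulators' scores in KO replicates 1, 2 and 3 were −0.23, −0.1 and 0.02, opposite in order to those of heart muscle markers (1.74, 0.62 and −0.25). Such orders over 3 libraries, here and below, can arise by chance and were not tested. Without KO replicate 1 Myocd had −0.25, and with Hox genes of paralogue groups 9 and above as a covariate Myocd had −0.165. The contractile median was −0.08 without KO replicate 1, −0.22 without KO replicate 2 and −0.075 without KO replicate 3, and with KO replicates 1 and 3 both left out it was 0.026 in the 1 KO library that remained. The regulators' call was lost without WT replicate 1 (−0.078), WT replicate 3 (−0.041) or KO replicate 1 (−0.09), and the median was −0.16 without WT replicate 2. That call was also lost with the Hox covariate (−0.079, adjusted p = 0.135) and with WT replicate 3 and KO replicate 1 both left out (−0.104, 0.134).

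Genes of vasoactive receptors and their signalling ranked lower, with 22 of 25 below 0 and a median log2 of −0.34 (camera adjusted p = 0.000102; adjusted p = 0.692 with an estimated correlation). Its member Pde3a, a phosphodiesterase that breaks down cyclic AMP, measured 508 ± 40.4 CPM in WT and 377 ± 16.9 in KO (−0.43 ± 0.082) and passed adjusted over the list alone (0.0234), the only member to do so. The endothelin receptor Ednrb had −1.70 ± 0.469. Pericyte markers had 9 of 12 genes below 0 and a median of −0.18 (camera adjusted p = 0.0178; adjusted p = 0.692 with an estimated correlation), with the potassium channel subunits Abcc9 (−0.36 ± 0.092) and Kcnj8 (−0.35 ± 0.116) first. Rgs5, a member of both lists, measured 4860, 4730 and 4200 CPM in WT replicates 1, 2 and 3 and 335, 1670 and 3490 in KO replicates 1, 2 and 3 (adjusted p = 0.386). It counts in both list scores below, and no score without it was made. The order of the pericyte scores, over 12 genes, therefore cannot be told apart from that of Rgs5 itself. List scores in KO replicates 1, 2 and 3 were −0.71, −0.42 and −0.22 for the vasoactive genes and −0.45, −0.35 and −0.04 for the pericyte markers. Hox genes of paralogue groups 9 and above (Hoxa10 left out), which are expressed in posterior parts of the body, moved alongside, with median log2 differences from WT of −1.8, −0.93 and −0.03 in those libraries. Heart muscle markers, not called as a list (median 0.79, camera adjusted p = 0.08), moved the other way, with scores of 1.74, 0.62 and −0.25. With these genes and Hoxa10 as a covariate, added after the data were seen, the vasoactive median was −0.14 (camera adjusted p = 0.013) and the pericyte call was lost (adjusted p = 0.0597). Without KO replicate 1, the medians were −0.21 and −0.11. The pericyte call was lost without WT replicate 1 (adjusted p = 0.0933).

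Collagen genes ranked lower, with 16 of 19 below 0 and a median log2 of −0.26 (camera adjusted p = 0.000401; adjusted p = 0.692 with an estimated correlation). The basement membrane chains Col4a5 (577 ± 32.3 CPM in WT, 457 ± 63.8 in KO, −0.34 ± 0.111) and Col4a1 (1650 ± 127 and 1260 ± 222 CPM, −0.40 ± 0.137) had the smallest p, and 0 members passed in edgeR or DESeq2. TGF-beta and BMP signalling genes had 21 of 29 below 0 and a median of −0.18 (camera adjusted p = 0.0178; adjusted p = 0.693 with an estimated correlation), with 0 passing in edgeR or DESeq2. The shared signal transducer Smad4 measured 69.9 ± 1.34 and 60.3 ± 1.33 CPM (−0.21 ± 0.051), and the receptor Tgfbr1 had −0.28 ± 0.075. Without KO replicate 1 the TGF-beta median was −0.031 and the call was lost (adjusted p = 0.193), and without WT replicate 2 it was −0.11. Its scores in KO replicates 1, 2 and 3 were −0.39, −0.12 and −0.03 and those of collagens −0.26, −0.19 and −0.14, also opposite in order to the heart muscle scores. In WT replicates 1, 2 and 3 the heart muscle scores were −0.23, 0.26 and −0.02. There the TGF-beta scores (−0.04, 0.03 and 0.01) had the same order, and the collagen scores (0, −0.03 and 0.04) had neither. With the Hox covariate the TGF-beta median was −0.009 (adjusted p = 0.724), that of collagens −0.17 and that of sex-linked genes −0.13 (adjusted p = 0.214). The 5 sex-linked genes tested had a median of −0.46 (camera adjusted p = 0.0357; adjusted p = 0.692 with an estimated correlation). Of the Y-linked genes, Uty measured 9.7, 18 and 18.6 CPM in KO replicates 1, 2 and 3 against 20.8 to 22.9 in WT, and Eif2s3y 33, 47.2 and 50.7 CPM against 54.1 to 56.5. The sex-linked scores in KO replicates 1, 2 and 3 were −0.85, −0.08 and −0.38. Ddx3y (93.1 and 90.8 CPM) and Kdm5d (22.3 and 23.7 CPM) also lay close together in KO replicates 2 and 3. The gap in the score between those libraries therefore does not describe the Y-linked genes. The sex-linked median was −0.22 without KO replicate 1, and the call was lost without each WT replicate or KO replicate 3 (adjusted p between 0.0526 and 0.0694).

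Interferon response genes ranked higher in KO, with all 31 tested members above 0 and a median log2 of 1.05 (camera adjusted p = 6.71e-06; adjusted p = 0.693 with an estimated correlation). In edgeR none passed over all genes or adjusted over the list alone, and DESeq2 called Stat2 (adjusted p = 0.0494). Mx2, which the annotation types as a polymorphic pseudogene, measured 1.1 ± 0.24 CPM in WT and 2.35 ± 0.29 in KO (1.08 ± 0.253). The transcription factor Stat2 measured 17.1 ± 2.35 and 30.5 ± 12.7 CPM (0.83 ± 0.267). The list score was 0.33, 0.26 and 1.81 in KO replicates 1, 2 and 3, and without KO replicate 3 the median was 0.24 (camera adjusted p = 0.00211) and Stat2 had 0.44. Endothelial markers had 17 of 20 genes above 0 and a median of 0.41 (camera adjusted p = 0.0357; adjusted p = 0.835 with an estimated correlation), with Flt1 at 0.26 ± 0.101 and Cldn5 at 0.58 ± 0.242 (0.37 without KO replicate 3). Their score also stood highest in KO replicate 3 (0.72, against 0.18 and −0.09 in KO replicates 1 and 2). Scores of some other cell types were high there too: in KO replicates 1, 2 and 3 they were 0.41, −0.61 and 0.93 for macrophages and myeloid cells, 0.14, −0.12 and 0.7 for adipocytes in general and 0.09, −0.22 and 0.94 for brown adipocytes. Scores not highest there were those of adventitial fibroblasts (0.53, −0.32 and 0.45), nerve and Schwann cells (0.59, −0.28 and 0.08), heart muscle (1.74, 0.62 and −0.25), skeletal muscle (0.1, 0.02 and 0.07) and erythroid cells (−0.7, −0.87 and −1.03). Without KO replicate 3 the endothelial median was 0.084 (adjusted p = 0.627), and the call was also lost without WT replicate 2 (0.31) or WT replicate 3 (0.29).

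The 7 mitochondrially encoded genes tested were all above 0, with a median log2 of 0.89 (camera adjusted p = 0.00108; adjusted p = 0.692 with an estimated correlation), and 6 passed adjusted over the list alone, 0 over all genes. mt-Co1 measured 22900 ± 5260 CPM in WT and 45300 ± 15800 in KO (0.98 ± 0.289), and mt-Cytb 16200 ± 3630 and 31300 ± 11200 CPM (0.95 ± 0.287). With WT replicate 3 and KO replicate 1 both left out, the libraries of lowest and highest mitochondrial share (5.66% and 18.9%), the median was 0.40 (camera adjusted p = 0.0112). Cell cycle genes had 23 of 27 above 0 and a median of 0.43 (camera adjusted p = 0.00172; adjusted p = 0.692 with an estimated correlation), at low levels: the proliferation marker Mki67 measured 1.82 ± 0.29 and 3.42 ± 1.92 CPM and the replication helicase subunit Mcm5 3.84 ± 0.323 and 5.16 ± 0.315 CPM. Mki67 had a log2 fold change of 0.91 ± 0.385, and of 0.34 without KO replicate 3. The list median was 0.28 without KO replicate 3 and 0.10 with genes of a mean count under 50 left out (adjusted p = 0.107). Noncoding RNA genes of smooth muscle and vessels had 19 of 20 above 0 and a median of 0.13 (camera adjusted p = 0.00347; adjusted p = 0.692 with an estimated correlation). Among them 3 passed adjusted over the list alone, including Neat1, the RNA scaffold of nuclear paraspeckles, at 358 ± 61.3 and 634 ± 163 CPM (0.83 ± 0.194), and Meg3, an imprinted transcript, at 56.3 ± 4.58 and 73.7 ± 7.23 CPM (0.39 ± 0.092). Scores of noncoding RNA genes in KO replicates 1, 2 and 3 were 0.31, 0.17 and 0.08, in the order of the heart muscle scores. In WT replicates 1, 2 and 3 that order was not shared (0.12, 0.05 and −0.17 against −0.23, 0.26 and −0.02). The noncoding median was 0.29 without WT replicate 2, 0.075 without KO replicate 1 and 0.23 without KO replicate 3, and the call was lost without WT replicate 3 (adjusted p = 0.0573). The call was also lost with the Hox covariate (0.083, adjusted p = 0.0899) and with WT replicate 3 and KO replicate 1 both left out (0.092, 0.217).

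**Figure D3:**
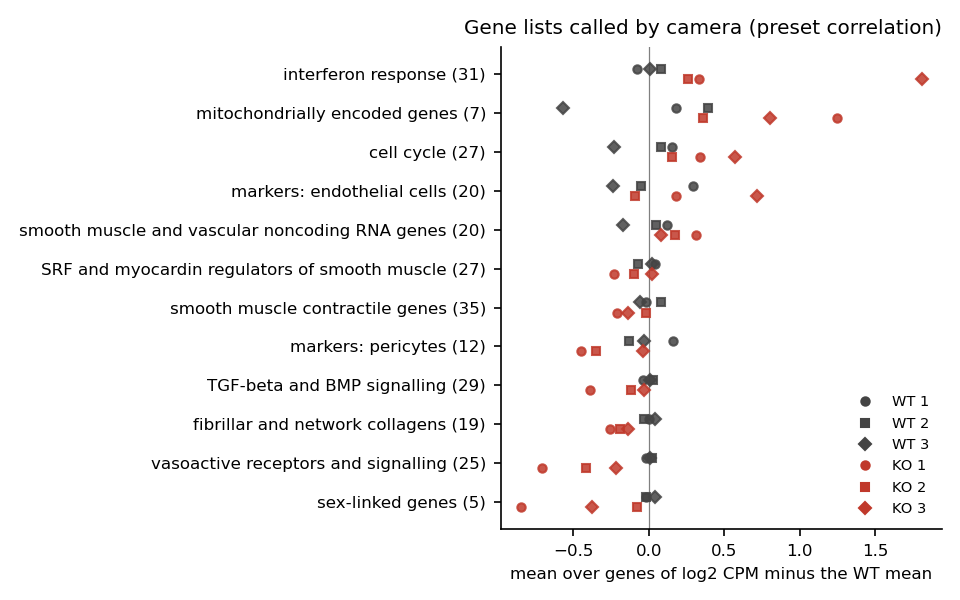
Score of the 12 called gene lists in each library, as the mean over tested genes (number in brackets) of log2 CPM minus the WT mean, with grey for WT, red for KO and the marker shape for the replicate number. KO replicate 3 lies at 1.81 for the interferon list, and KO replicate 1 at −0.71 for the vasoactive list.

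Of the 37 lists tested, camera called 7 lower and 5 higher, none with an estimated correlation (smallest adjusted p = 0.692). With KO replicates 1 and 3 both left out, a choice made after the data were seen, 1 KO library remained, which the fit assumes to vary like the WT libraries, so its calls describe that library and the medians are given as values. They were 0.40 for mitochondrially encoded genes, 0.13 for cell cycle genes, −0.093 for the regulators of contractile genes, −0.074 for TGF-beta genes, −0.26 for sex-linked genes, −0.02 for endothelial markers, 0.15 for interferon genes, −0.14 for collagens, −0.18 for vasoactive genes, −0.38 for pericyte markers and 0.17 for noncoding RNA genes. Over all lists, 12 members passed in edgeR adjusted over the list alone; those outside the called lists were Atf6, a sensor of unfolded proteins (−0.28 ± 0.053), and the muscle enolase Eno3 (0.53 ± 0.123). Fry called 0 lists in a single direction, and p53 targets and apoptosis genes in either direction (adjusted p = 0.00436). Markers of other cell types that were not called were heart muscle (median 0.79, adjusted p = 0.08), erythroid cells (−1.38, 0.137), macrophages and myeloid cells (0.34, 0.259), adventitial fibroblasts (0.14, 0.259), adipocytes in general (0.24, 0.363), brown adipocytes (0.23, 0.627), skeletal muscle (0.064, 0.585) and nerve and Schwann cells (0.14, 0.88). Lymphocyte and mesothelial markers had fewer than 5 tested genes each. Elastic fibre genes (−0.071, 0.233), matrix proteases (−0.13, 0.171), calcium handling genes (−0.12, 0.121) and Hox position genes (−0.14, 0.171) did not pass as lists. Among their members, DESeq2 called Fbn1 and Eln of the elastic fibres as lower (log2 −0.49 and −0.70, adjusted p = 0.022 and 0.0269). It also called the protease Mmp14 (0.0351) and the channel subunit Abcc9 (0.0201) as lower, and none as higher. In edgeR no member of these lists passed. Markers of smooth muscle phenotypic modulation had a median of 0.074 and a mean of 0.081 with a test direction of lower (adjusted p = 0.696). Signs also differed for circadian clock genes (median 0.55, mean −0.018), the unfolded protein response (−0.057 and 0.011) and chondrogenic and osteogenic genes (median 0.011, tested lower), none of which passed.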

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

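The replicate block, other normalization, filters, tools and single left-out libraries were planned; leaving out 2 libraries together and the Hox covariate were added after the data were seen. RP23-57D10.3 had 0 counts in every KO library under each setting. Its fitted log2 values depend on the prior count and are no bounds, and at least 277-fold lower is what the counts allow. The fitted value was −11.219 with the replicate block (adjusted p = 0.224), −11.355 with WT replicate 3 and KO replicate 1 both left out (0.0769) and −10.456 with the Hox covariate (0.107), and each of these 3 settings left 0 lower genes. Leaving out single libraries gave −11.302 to −11.087 (adjusted p 0.00467 to 0.131), with 0 to 1 lower and 0 to 2 higher genes; the 2 higher genes, without KO replicate 2, were RP23-8J15.5 and RP23-8J15.4. Without a filter there were 5 higher and 4 lower genes, and in DESeq2 60 and 139, where RP23-57D10.3 had no adjusted p. The cause of these differences was not tested. Same-numbered WT and KO libraries deviated together with correlations of 0.11, 0.13 and −0.06, and not every library correlated best with its own number. Deviations from a mean of 3 libraries depend on each other, so these correlations cannot exclude a pairing. The numbers are not taken as pairs because the sources do not say what a replicate number shares. The block also ended the endothelial call (0.373, adjusted p = 0.0622).

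Of 12 called lists, 0 were called with an estimated correlation or by fry. The contractile median of −0.128 had adjusted p = 0.692 with an estimated correlation and 0.444 in fry, which does not compare it with other genes, and was 0.026 (0.548) with KO replicates 1 and 3 both left out, which leaves 1 KO library, assumed to vary like the WT libraries; single left-out libraries gave −0.218 to −0.075, all called. With KO replicates 1 and 3 left out, Acta2 (0.133), Myh11 (0.052), Tagln (0.073), Cnn1 (0.03) and endothelial markers (−0.02) changed sign. Tagln was also 0.029 with the Hox covariate and lay between −0.157 and 0.007 over single left-out libraries. With WT replicate 3 and KO replicate 1 both left out, calls were lost for regulator (−0.104, 0.134), TGF-beta (−0.049, 0.233), noncoding RNA (0.092, 0.217) and endothelial genes (0.364, 0.217). With the Hox covariate, calls were lost for TGF-beta (−0.009, adjusted p = 0.724), sex-linked (−0.128, 0.214), regulator (−0.079, 0.135), noncoding RNA (0.083, 0.0899) and pericyte genes (−0.155, 0.0597). They were kept for contractile (−0.134), vasoactive (−0.143), collagen (−0.168), mitochondrially encoded (0.646), cell cycle (0.469), endothelial (0.684) and interferon genes (1.633). Over all settings, 631 values of 42 named genes kept direction and side of the threshold, 21 gained a call, 4 lost a call and 6 changed sign; of the lists, 135 values were kept and 54 lost a call. The median log2 fold change of all genes was 0.012 with TMM and 0.008 with DESeq2 size factors. At this depth, 0 counts over the KO group allow up to 0.0473 CPM.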

Other observations

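The splits of the libraries were chosen before their results were seen; the tests on Dhx32, KO replicate 1 and WT replicate 3 were chosen after. Clock genes stood apart in WT replicate 3. Arntl measured 33.7 CPM there against 0.433 to 3.57 in the other 5 libraries, and Npas2 51.6 against 3.82 to 11.8. Their targets went the other way, with Dbp at 43.6 CPM against 282 to 535 and Ciart at 0.828 against 12.5 to 46.2. KO replicate 3 stood apart in immune genes. The interferon-induced GTPases Igtp and Iigp1 measured 73.6 and 145 CPM against at most 7.17 and 19.2 in the other libraries, and H2-Ab1, an antigen-presenting class II gene, measured 46.2 against at most 10.

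Of 13 mitochondrial protein genes, 6 had at most 30 counts summed over the 6 libraries: mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l. Between Tubb4b-ps2 and Lmbrd1 on chromosome 1, GENCODE M21 places 7 pseudogenes whose best matches were mt-Nd4, mt-Nd4l, mt-Nd3, mt-Co3, mt-Atp6, mt-Co2 and mt-Co1, at 99.71% to 100% identity. The copies of mt-Nd4 and mt-Co1 are 876 and 492 bases long, and these genes had at least 130644 and 422503 counts in each library. mt-Atp8 was the best match of none. The table holds 7 rows between these genes, RP23-8J15.1 to RP23-8J15.7 by name, which were not matched to single pseudogenes. RP23-8J15.4 had 7, 6 and 1 counts in WT replicates 1, 2 and 3 and 460, 4 and 415 in KO replicates 1, 2 and 3.

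With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 1 called gene and the highest of the others 0, so 1 split gave as many. It gave 2060 genes at an unadjusted p under 0.05 and the highest of the others 1103, again with 1 split as high. For gene lists it gave 12 and the highest of the others 23, from WT replicates 1 and 3 with KO replicate 3 against the rest, and 5 of the 10 splits gave at least 12.

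Dhx32 had lower values in KO beside RP23-57D10.3. A change shared with the upstream genes is argued against by the 9 other tested genes within 1 Mb, most of them upstream. Their median log2 fold change was 0.002 ± 0.073 (SE), above −0.317, which is 50% of the change of Dhx32. Downstream, that window held only Adam12 (−0.437 ± 0.508), and Dock1, the next tested gene, had −0.263 ± 0.076. Further on, Mki67 (0.911 ± 0.385) and Ebf3 (0.727 ± 0.325) lay above 0. A change shared with the nearest downstream genes stays open. A flanking chromosome segment from another strain stays open: 7 of 31 genes within 5 Mb had an unadjusted p under 0.05 (22.6%, exact 95% interval 9.59 to 41.1) against 15.1% elsewhere (one-sided Fisher's exact p = 0.18). A direct effect of the knockout on Dhx32, through the altered DNA or the lost transcript, stays open and was not tested. That RP23-57D10.3 may be the targeted transcript is a hypothesis from its 0 counts in KO, and no value here ties that name to Mymsl.

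In KO replicate 1, Rgs5 and Kit were at 7.28% and 4.24% of the WT mean. A lower share of smooth muscle cells as the whole cause of falls of that size is argued against by the contractile genes. Their median stood at 85.5% of the WT mean in that library. A smaller fall in that share stays open, with Acta2 at 77.3% and Myh11 at 74.7%. Less of the distal aorta in the dissection is a candidate explanation: the 6 tested Hox genes of paralogue groups 9 and above, without Hoxa10, had a median log2 difference from WT of −1.8 in KO replicate 1, and the 19 genes of groups 1 to 8 had 0.03 (exact permutation p over genes, which are not independent, 0.001, adjusted over the 6 libraries 0.0057). The difference was −0.93 in KO replicate 2 (adjusted 0.0057) and −0.03 in KO replicate 3 (adjusted 0.59), and heart muscle markers, as a list not called, moved the other way with scores of 1.74, 0.62 and −0.25 in KO replicates 1, 2 and 3. The list of Hox position genes fixed beforehand, 24 of them tested, was not called (median −0.136, camera adjusted p = 0.171). Not every gene followed the grouping. Hoxb9 had 3.2 CPM in KO replicate 1 against 2.22 to 3.89 in WT. Hoxd8, of group 8, had 0.928 CPM there against 5.18 to 8.07 in WT. Levels were low: Hoxa11 had 0.745 to 2.15 CPM in WT and Hoxa9, the highest of the 6, 8.16 to 13.4. An effect of the knockout that differs between animals stays open and was not tested.

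For the clock genes of WT replicate 3, a knockout effect of that size is argued against by WT replicate 2. It differed from the KO mean by a median of 0.133 (log2, absolute, 15 genes, with Arntl, Npas2, Dbp and Ciart left out) and from WT replicate 3 by 1.95. WT replicate 1 was not part of this test and lay on the side of WT replicate 3. Its Arntl (3.57 CPM) and Npas2 (11.8) were above every KO library (at most 0.567 and 6.02). Its Dbp (282) and Ciart (12.5) were below every KO library (at least 343 and 22.4). WT replicate 2 lay just outside the KO libraries on that side for Arntl (0.675 CPM) and Dbp (335). It lay within their range for Npas2 (4.09) and Ciart (32.3). A smaller knockout effect on clock genes therefore stays open. Tissue taken at another time of day is a candidate explanation. Of 8 further genes of opposite phase, 2 predicted higher and 6 predicted lower from textbook knowledge, all 8 lay outside the range of the other 5 libraries in the predicted direction. No other explanation of the difference of WT replicate 3 from the other libraries was tested.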
